A study of Homo sapiens with 6 samples.

How the data were processed

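RNA sequencing of total RNA had been carried out on 6 libraries of H9 cells, an established human embryonic stem cell line. The libraries fell into 2 groups of 3, given by their titles: cells treated with a small interfering RNA against NPM1 (siNPM1, with a treatment label that names B23, another name of the NPM1 protein) and cells treated with a control duplex (siControl). The series design describes the 3 samples of each group as biological replicates. The treatment label of the third siNPM1 sample carries an added 3, which the matching column names show to be the replicate number.

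The authors deposited 1 table of TPM values with 62703 genes, of which 41737 have a symbol in the table, and the mean TPM of each group. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, the annotation release, the strand setting and the read length were not given in the sources used here. Each library's TPM values sum to the same total, so TPM keeps no sequencing depth: the depth is unknown, and no counting interval or detection floor can be given. A value of 0 is described only as listed at 0. Where a short transcript lies inside a longer one, or a pseudogene resembles its parent gene, the assignment of reads by the authors' counting cannot be followed from TPM values. The 6 library columns were matched to samples by name, and the authors' 2 mean columns were not used in any test.

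Values were analysed as log2(TPM + 1), with a pseudocount of 1, over 15768 genes with a mean of at least 1 TPM over the 6 libraries. The groups were compared with limma 3.58.1 in R 4.3.3, with a variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was the threshold. Fold changes are given as siNPM1 minus siControl on the log2(TPM + 1) scale, which understates the change of genes with low values. The standard error is that of the moderated fit. For single genes, a two-sided exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

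Before the data were examined, 29 gene lists were fixed, covering pluripotency, lineages, signalling pathways, stress responses, the cell cycle, the nucleolus, ribosomal proteins and mitochondrially encoded genes. All 855 entries were matched to the table. Lists with at least 5 tested members, 27 of them, were tested with camera (limma) at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares the members with all other tested genes. An estimated inter-gene correlation and fry, which tests whether the members move on balance in one direction, were run beside it. The number of members past the threshold is given over all genes tested and adjusted over the list alone.

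The rule for named genes was also fixed before the data were examined. It takes NPM1, NPM2, NPM3, ESRG, BMP4, POU5F1, SOX2 and NANOG whatever their values. It then takes the 10 higher and the 10 lower genes with the largest change among those past the threshold, with a symbol, at least 5 TPM in the higher group and no overlap between the groups. Pseudogenes and bare clone identifiers are left out. Where fewer than 10 pass in a direction, the genes with the smallest p follow and are named as not past the threshold. From each list, up to 2 higher and 2 lower members past the threshold are taken, or the 2 members with the smallest p where none pass. Other genes named below were chosen after their values were seen, and this is said beside them. Positions and gene types come from GENCODE release 29 on GRCh38, in which 58279 of the gene identifiers (92.9%) were found.

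The test was checked on simulated data for the comparison of siNPM1 with siControl. Values were drawn for the 15768 genes with each gene's residual SD over the 6 libraries, and known changes were added to some of them. Of 100 genes shifted by 1 on the log2 scale, 31 were recovered, and of 100 shifted by 2, 71 were recovered, with 8 unshifted genes past the threshold. With the residual SDs that remain without siControl replicate 2, the test recovered 65 and 87. A list of 35 p53 targets shifted by 0.5 was recovered (camera, adjusted p = 5.58e-16), and 0 other lists passed. The simulated genes were drawn independently, so this check does not cover false calls of lists whose members vary together. Nor do such draws hold a shift of a single library shared over many genes. Adding many changes at once also eases the Benjamini-Hochberg cutoff. The recovered numbers may therefore be higher than the test would reach in the real values. In the real values the estimated inter-gene correlation reached 0.977, for mitochondrially encoded genes.

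The alternatives set before the data were examined were other pseudocounts, other filters on low values, centring, quantile normalization, rescaling without mitochondrial and ribosomal protein genes, the replicate number as a block, other forms of the variance prior, array weights, a minimum fold change, and leaving out each library in turn. A fit with siControl replicate 2 as the only control, and a fit with GC and length trends removed, were added after the data were seen. Where siControl replicate 2 is the only control, the residual spread comes from the 3 siNPM1 libraries alone. The p-values of that fit therefore do not measure the spread between control libraries. Figures were drawn with Matplotlib 3.10.9.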

Results

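Transcript levels were measured by RNA sequencing in H9 human embryonic stem cells, a pluripotent line, after treatment with a small interfering RNA against NPM1 (3 libraries, siNPM1) or with a control duplex (3 libraries, siControl). NPM1 encodes nucleophosmin, an abundant nucleolar protein and histone chaperone also called B23. The series title places NPM1 beside ESRG, a long noncoding RNA of human pluripotent cells, BMP4 protein and TGF-β signalling, so the comparison asks which transcripts differ once NPM1 is lowered. Protein was not measured here. Between 23970 and 26454 genes were listed above 0 in each library, and between 14998 and 15993 reached 1 TPM. The sequencing depth behind these values is unknown, so differences are judged against the spread between replicates.

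NPM1 transcript was reduced in each of the 3 siNPM1 libraries. NPM1 (ENSG00000181163, protein-coding, GRCh38 chromosome 5, 171387116 to 171411137, plus strand) stood at 3109, 2969 and 3132 TPM in siControl replicates 1, 2 and 3. In siNPM1 replicates 1, 2 and 3 it stood at 173, 165 and 238 TPM. The level left was 6.26% ± 1.31 (SD, n = 3) of the siControl mean, a log2 fold change of -4.01 with a standard error of 0.157 (limma, adjusted p = 0.000852). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 can give. The paralogs NPM2 and NPM3 did not pass, although NPM2 fell just under the threshold without siControl replicate 2 (log2 fold change 2.11, adjusted p = 0.04999 in limma). NPM2 stood at 2.68 ± 1.49 TPM in siControl and 14.0 ± 10.5 in siNPM1 (log2 fold change 1.91, adjusted p = 0.216, SD, n = 3 each, limma), with siNPM1 replicate 1 at 26.1, and NPM3 at 148 ± 10.03 and 143 ± 10.3.

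Apart from NPM1, 3 transcripts fell past the threshold, and 0 genes rose past it (limma, Benjamini-Hochberg adjusted p under 0.05, 15768 genes). The first pair are annotated as processed pseudogenes of NPM1, so the assignment of their reads is uncertain, although only 9.31% of the 50-base stretches of NPM1P46 and 0% of those of NPM1P51 occur exactly in NPM1. NPM1P46 (chromosome 2, 197379701 to 197380892) went from 7.31 ± 1.56 to 0.187 ± 0.0586 TPM (adjusted p = 0.0282), and NPM1P51 (chromosome 6, 41666906 to 41667649) from 9.09 ± 0.574 to 0.587 ± 0.338 TPM (adjusted p = 0.0286, SD, n = 3 each, limma). The remaining one, ENSG00000277941, has no symbol in the table and is annotated as a noncoding RNA of 149 bases (chromosome 22, 26671402 to 26671550). It was listed at 40.5, 32.4 and 102 TPM in the siControl libraries and at 0 in each siNPM1 library (adjusted p = 0.0235). It lies inside the long noncoding RNA MIAT (chromosome 22, 26646428 to 26676475, same strand), so reads could be split between them. MIAT itself was at 24.7, 17.9 and 21.1 TPM in siControl and 44.0, 23.8 and 24.4 TPM in siNPM1. The 2 pseudogenes and this transcript fall outside the rule for named genes and were named after their values were seen.

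At an unadjusted p under 0.05 there were 2085 higher and 1017 lower genes, 19.7% of those tested. The groups did not overlap for 2562 higher and 1348 lower genes, 24.8% of those tested where chance gives 10%. Another grouping, siControl replicates 1 and 3 with siNPM1 replicate 1 against the rest, gave more of both: 3559 genes at an unadjusted p under 0.05 and 27.1% without overlap. The median log2 fold change over all tested genes was 0.10 and -0.02 after centring each library on its median, so fold changes near this size carry no direction. The count of genes past the threshold depended on siControl replicate 2: without it 5833 genes passed, 3805 higher and 2028 lower, and 2497 of these (42.8%) had the opposite sign against that replicate alone, as had 45.2% of all tested genes between these fits. ENSG00000277941 was lower in both of these fits (log2 fold change -6.03 without siControl replicate 2 and -5.06 against it alone). With siControl replicate 2 as the only control, the residual spread comes from the siNPM1 libraries alone. A transcript listed at 0 in each of them, as this one is, has no spread of its own there. Passing in that fit therefore favours such transcripts and was not read as robustness or as a direction. Leaving out siControl replicate 1 or siNPM1 replicate 3 left 1 gene, and leaving out siNPM1 replicate 1 gave 11.

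**Figure D1:**
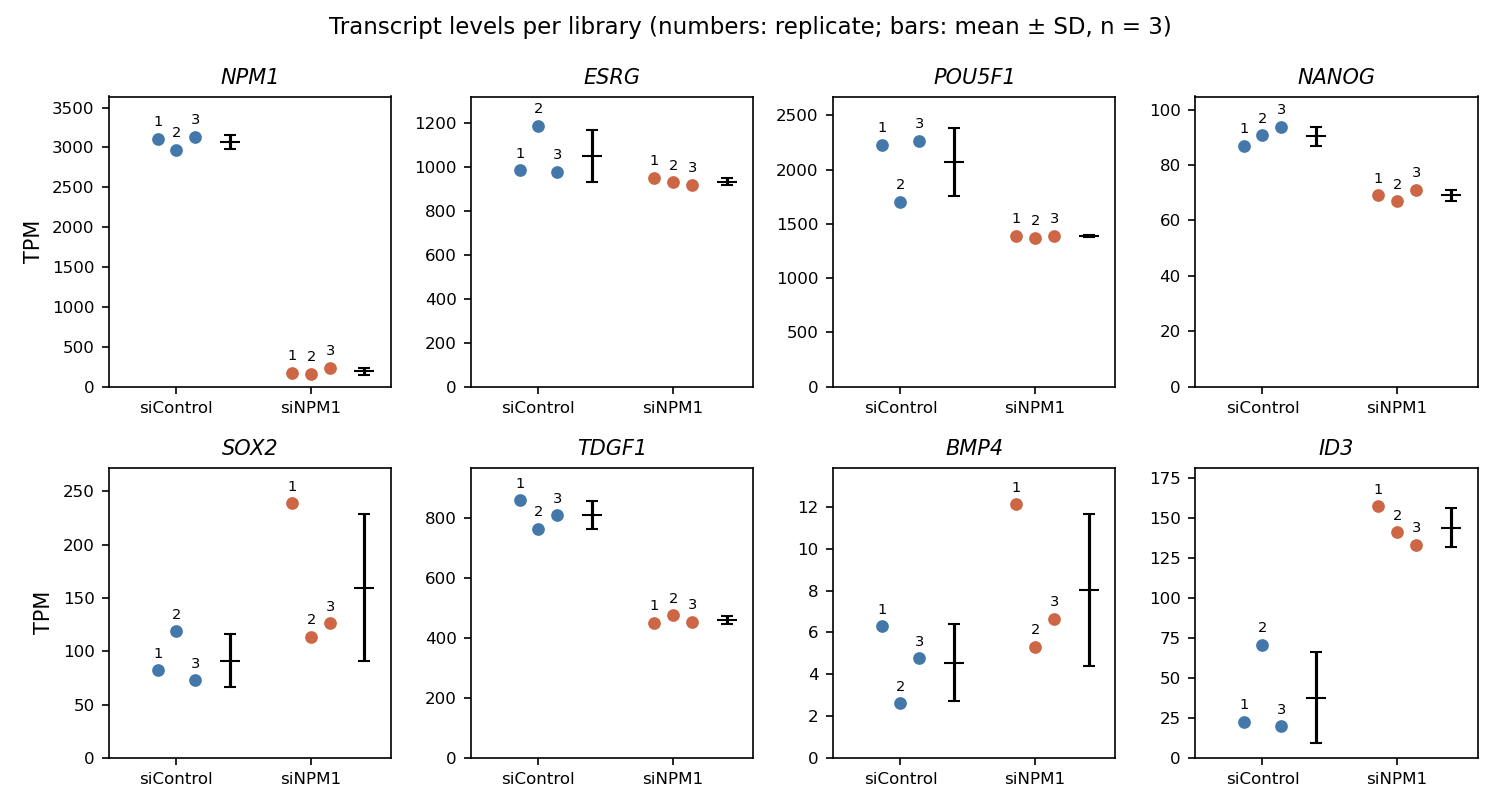
TPM (linear vertical axis from 0) of 8 genes in each of the 3 siControl and 3 siNPM1 libraries, numbered by replicate, with the mean ± SD of each group beside the points. NPM1 lay between 165 and 238 TPM in siNPM1 and above 2968 TPM in siControl, while BMP4 and SOX2 overlapped between the groups.

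The 6 libraries did not separate by group. On the first principal component, which held 54.4% of the variance, siControl replicates 1 and 3 lay at -60.0 and -61.7, and siControl replicate 2 lay at 28.1 beside the siNPM1 libraries at 30.4 to 32.2. Pearson's r over genes was 0.977 between siControl replicates 1 and 3, 0.923 and 0.917 between replicate 2 and each of them, and 0.945 to 0.963 between replicate 2 and the siNPM1 libraries. Mitochondrially encoded protein transcripts made up 8.86% and 8.83% of the total in siControl replicates 1 and 3, 22.3% in replicate 2, and 17.0% to 19.8% in siNPM1. Ribosomal protein transcripts made up 25.2% and 25.7%, 17.6%, and 20.3% to 22.5% in the same order. NPM1 itself was at the control level in siControl replicate 2. siNPM1 replicate 1 stood apart on the second component, at 48.7 (17.5% of the variance).

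**Figure D2:**
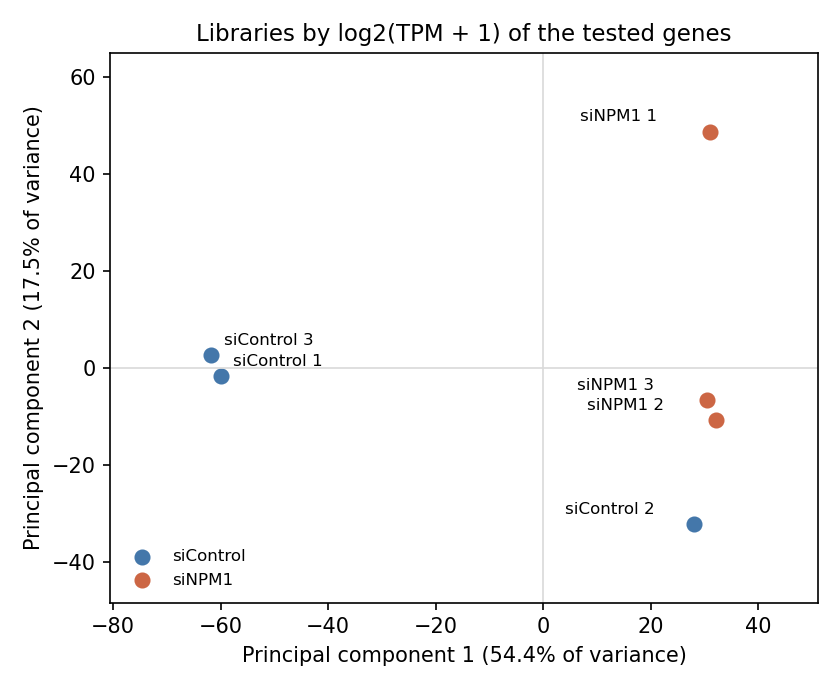
First and second principal components (arbitrary units, with their share of the variance) of log2(TPM + 1) over the 15768 tested genes, each point 1 library, coloured by group and labelled by replicate. siControl replicate 2 lies at 28.1 on the first component, near the siNPM1 libraries at 30.4 to 32.2 and far from siControl replicates 1 and 3 at -60.0 and -61.7.

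ESRG and BMP4, named in the series title beside NPM1, and the core pluripotency factors did not pass the threshold. ESRG (ENSG00000265992, chromosome 3, 54632122 to 54639857, minus strand) stood at 1049 ± 119 TPM in siControl and 931 ± 16.4 in siNPM1 (log2 fold change -0.17, adjusted p = 0.425). BMP4 (ENSG00000125378, chromosome 14, 53949736 to 53958761, minus strand) stood at 4.56 ± 1.85 and 8.03 ± 3.62 TPM (log2 fold change 0.69, adjusted p = 0.318), and its groups overlapped. POU5F1, which encodes OCT4 (chromosome 6, 31164337 to 31180731), was at 2068 ± 314 and 1387 ± 10.3 TPM (log2 fold change -0.56, adjusted p = 0.212). NANOG (chromosome 12, 7787794 to 7799141) was at 90.4 ± 3.44 and 69.0 ± 2.00 TPM (log2 fold change -0.38, adjusted p = 0.212). SOX2 (chromosome 3, 181711924 to 181714436) was at 91.3 ± 24.5 and 159 ± 69.0 TPM (log2 fold change 0.75, adjusted p = 0.255), with siNPM1 replicate 1 at 239. All values are mean ± SD of 3 libraries, with limma's adjusted p. Without siControl replicate 2, POU5F1 (log2 fold change -0.70, adjusted p = 0.00192) and NANOG (log2 fold change -0.38, adjusted p = 0.0155) passed as lower, and ESRG (log2 fold change -0.07, adjusted p = 0.329), BMP4 (log2 fold change 0.41, adjusted p = 0.383) and SOX2 (log2 fold change 0.95, adjusted p = 0.0742) did not. Against siControl replicate 2 alone none of the 5 passed: POU5F1 had a log2 fold change of -0.30 (adjusted p = 0.446), NANOG -0.39 (adjusted p = 0.424), ESRG -0.35 (adjusted p = 0.424), BMP4 1.25 (adjusted p = 0.480) and SOX2 0.34 (adjusted p = 0.812).

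Of the 35 pluripotency genes tested, 21 had a positive and 14 a negative log2 fold change, and 0 passed over all genes. Adjusted over the list alone, 2 higher and 3 lower ones passed. The lower ones were TDGF1, POU5F1 and NANOG. TDGF1, the nodal co-receptor CRIPTO, stood at 811 ± 47.1 TPM in siControl and 460 ± 13.6 in siNPM1 (log2 fold change -0.81, adjusted p = 0.1002). CDH1, which encodes E-cadherin, stood at 121 ± 2.67 and 170 ± 17.7 TPM (adjusted p = 0.198). The list as a whole did not pass (camera, adjusted p = 0.576). Of 12 naive pluripotency genes tested, 8 were positive, 0 passed over all genes and 2 higher ones passed adjusted over the list alone (camera, adjusted p = 0.283). The naive median was 0.72 against siControl replicate 2 alone. Without that replicate it was 0.32 and the list did not pass (camera, adjusted p = 0.983). Nor did the list pass with all 6 libraries and an estimated correlation (camera, adjusted p = 0.662). Those adjusted over the list alone were DPPA3, at 1.35 ± 0.673 and 6.33 ± 0.734 TPM, and TBX3, at 0.290 ± 0.176 and 3.05 ± 0.734 TPM (adjusted p = 0.134 for each over all genes, SD, n = 3, limma).

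Besides NPM1, no gene with a symbol outside its pseudogenes passed, and the genes with the smallest p are given as values not past the threshold, all of them without overlap between the groups. Those higher in siNPM1 had adjusted p from 0.1002 to 0.1404. SORBS2, a cytoskeletal adaptor, was at 19.4 ± 2.41 and 48.6 ± 2.97 TPM, and PPP1R1B, a phosphatase inhibitor, at 15.1 ± 2.05 and 36.4 ± 1.86 TPM. The receptors ERBB2, NRP2 and AXL had log2 fold changes of 1.26, 1.14 and 1.19. PYGM, the muscle glycogen phosphorylase, had 1.61, DCLK1, a microtubule-associated kinase, 1.20, CTSV, a lysosomal protease, 0.77, IFI6, an interferon-induced gene, 1.37, and DPPA3 1.67. Those lower in siNPM1 had adjusted p from 0.1002 to 0.105. YWHAE, which encodes the 14-3-3 epsilon protein, was at 687 ± 39.4 and 304 ± 46.7 TPM. GPC6, a cell-surface proteoglycan, was at 16.9 ± 3.08 and 4.90 ± 0.235 TPM, and TNMD at 21.5 ± 1.65 and 6.12 ± 1.63 TPM (SD, n = 3 each). PANCR, a long noncoding RNA, had a log2 fold change of -1.44, ADCY2, an adenylate cyclase, -1.35, ARHGEF35 -1.20, PAFAH1B2 -0.97, AKAP7, an anchoring protein of protein kinase A, -0.90 and TDGF1 -0.81. ARHGEF35 resembles its paralog ARHGEF5, so its value is uncertain. Each of these 19 genes passed without siControl replicate 2, and none against it alone.

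Camera placed BMP targets higher and activin and nodal targets lower in siNPM1, but the list medians overlapped between the groups. Relative to each gene's mean, BMP target medians were -0.612, 0.0342 and -0.667 in siControl replicates 1 to 3. In siNPM1 they were 0.916, -0.00766 and 0.0967. Activin and nodal target medians were -0.0699, 0.39 and -0.138 against -0.381, 0.076 and -0.0332. For these targets, siNPM1 replicates 2 and 3 lay above siControl replicates 1 and 3. Of 13 BMP targets tested, 11 were positive with a median log2 fold change of 0.69; 0 passed over all genes and 2 passed adjusted over the list alone (camera, adjusted p = 0.0293; adjusted p = 0.662 with an estimated correlation). ID3, an inhibitor of DNA binding induced by BMP, was at 22.5, 70.8 and 19.9 TPM in siControl and 158, 141 and 133 in siNPM1 (log2 fold change 2.14, adjusted p = 0.179), and TBX3 had a log2 fold change of 1.64. Of 16 activin and nodal targets in pluripotent cells, 12 were negative with a median of -0.36; 0 passed over all genes and 2 passed adjusted over the list alone (camera, adjusted p = 0.0227; adjusted p = 0.662 with an estimated correlation). TDGF1 and NANOG, given above, had its smallest p. BMP targets did not pass without siControl replicate 2 (median 0.98, adjusted p = 0.159) or siNPM1 replicate 1 (median 0.39, adjusted p = 0.181), and passed against siControl replicate 2 alone (median 0.40, adjusted p = 0.0477). They also did not pass with a mean of at least 5 TPM (median 0.69, adjusted p = 0.071), rescaled without mitochondrial and ribosomal protein genes (median 0.81, adjusted p = 0.0561) or with array weights (median 0.87, adjusted p = 0.253). Activin and nodal targets did not pass without siControl replicate 2 (median -0.08, adjusted p = 0.326) or siNPM1 replicate 1 (median -0.13, adjusted p = 0.181), and passed as lower against siControl replicate 2 alone (median -0.61, adjusted p = 3.69e-05). They also did not pass after centring (median -0.49, adjusted p = 0.0613) or with array weights (median -0.04, adjusted p = 0.604).

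The remaining signalling lists did not pass in camera at the settings of the report, and 0 of their members passed over all genes. Of 27 TGF-β ligands, receptors and SMADs, 13 were positive and 14 negative, and 1 higher and 3 lower members passed adjusted over the list alone (camera, adjusted p = 0.415). LTBP1, a latent TGF-β binding protein, was at 26.7 ± 0.894 and 16.4 ± 1.88 TPM (adjusted p = 0.176). Of 27 TGF-β targets in differentiated cells, 12 were positive and 15 negative, with 1 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.232). They were COL1A1, at 7.89 ± 2.01 and 17.0 ± 2.19 TPM, and FN1, which encodes fibronectin, at 136 ± 22.6 and 72.1 ± 8.54 TPM. The 16 BMP ligands, receptors and antagonists split 8 to 8, with 0 adjusted over the list alone (camera, adjusted p = 0.397). The activin receptor gene ACVR2B and the co-receptor gene RGMB had log2 fold changes of -0.73 and -0.60. Of 12 WNT targets 9 were positive, with 1 adjusted over the list alone (camera, adjusted p = 0.184; adjusted p = 0.0197 without a filter on low values). LEF1, a transcription factor of the pathway, was at 0.277 ± 0.119 and 3.23 ± 0.353 TPM, and FZD7 at 24.4 ± 13.4 and 42.8 ± 0.366 TPM. Of 18 FGF and ERK targets 11 were negative, with 0 adjusted over the list alone (camera, adjusted p = 0.158). FOSL1 had a log2 fold change of 1.01 and DUSP4 of -0.86, and the list passed without siNPM1 replicate 2 (adjusted p = 0.0467) or 3 (adjusted p = 0.0227). Of 21 YAP targets 14 were negative, with 2 higher adjusted over the list alone, AXL and FJX1 (log2 fold changes 1.19 and 1.36; camera, adjusted p = 0.232). The YAP list passed as lower without siControl replicate 2 (camera, adjusted p = 0.011), while its median against that replicate alone was 0.39. With all 6 libraries and an estimated correlation it did not pass (camera, adjusted p = 0.662).

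ATF4 targets, the amino acid and stress genes of the integrated stress response, and cholesterol synthesis genes were lower in siNPM1 as lists. In both, the medians of siControl replicates 1 and 3 stood above those of all other libraries, siControl replicate 2 among them. Of 28 ATF4 targets, 27 were negative with a median log2 fold change of -0.69; 0 passed over all genes and 4 lower ones passed adjusted over the list alone (camera, adjusted p = 1.51e-11; adjusted p = 0.662 with an estimated correlation). The serine synthesis enzyme PSAT1 was at 332 ± 10.1 TPM in siControl and 238 ± 11.8 in siNPM1, and the cystine transporter SLC7A11 at 16.8 ± 2.74 and 9.26 ± 0.249 TPM. The stress genes DDIT3 and ATF3, chosen after their values were seen, were high in siControl replicates 1 and 3 only. DDIT3 was at 234, 2.56 and 254 TPM in siControl and 16.7, 7.64 and 10.4 in siNPM1. ATF3 was at 352, 13.0 and 382 against 25.4, 24.6 and 28.9. Against siControl replicate 2 alone, 8 of the 28 targets were positive, DDIT3 and ATF3 among them. Of 25 cholesterol synthesis genes, 22 were negative with a median of -0.73; 0 passed over all genes or adjusted over the list alone (camera, adjusted p = 2.87e-07; adjusted p = 0.662 with an estimated correlation). INSIG1, a sterol-sensing regulator, was at 247, 60.5 and 248 TPM in siControl and 34.9, 39.4 and 44.0 in siNPM1. siControl replicate 2 lay near siNPM1 in both lists: against it alone the medians were -0.15 and -0.10, and without it -0.95 and -1.08.

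Genes of G2 and mitosis also fell as a list: 31 of 42 were negative, with a median log2 fold change of -0.22, and 0 passed over all genes or adjusted over the list alone (camera, adjusted p = 5.8e-06; adjusted p = 0.662 with an estimated correlation). PTTG1, which encodes securin, was at 597 ± 138 and 357 ± 22.6 TPM, and BIRC5, which encodes survivin, at 88.9 ± 7.56 and 66.3 ± 2.85 TPM. The list kept its direction and passed both without siControl replicate 2 (adjusted p = 0.000232) and against it alone (adjusted p = 3.69e-05; adjusted p = 0.638 with an estimated correlation), and these fits share the 3 siNPM1 libraries. The S phase list did not pass (34 of 38 positive, 0 adjusted over the list alone, camera, adjusted p = 0.115, and adjusted p = 0.723 with an estimated correlation). With all 6 libraries and the preset correlation, camera passed it as higher with a mean of at least 5 TPM (adjusted p = 0.0479) and quantile normalization (adjusted p = 0.0286). The same held with the replicate number as a block (adjusted p = 0.0378) and array weights (adjusted p = 7.64e-05). It had a median of 0.51 without siControl replicate 2 (adjusted p = 7.29e-06) and of -0.27 against that replicate alone (adjusted p = 5.63e-08). Among its members, RFC2 was at 41.8 ± 9.49 and 54.5 ± 5.03 TPM and TIPIN at 14.7 ± 8.72 and 22.5 ± 1.71 TPM.

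Ribosome biogenesis factors rose as a list, with most of the difference lost against siControl replicate 2 alone, and the other groups of the translation and mitochondrial machinery went one way or the other with the control library used. Of 70 ribosome biogenesis genes, 60 were positive with a median log2 fold change of 0.40; 0 passed over all genes or adjusted over the list alone (camera, adjusted p = 0.000127; adjusted p = 0.662 with an estimated correlation). EMG1, a ribosomal RNA methyltransferase, was at 10.6 ± 1.58 and 17.2 ± 1.99 TPM, and NMD3, an export adaptor of the large subunit, at 40.5 ± 7.80 and 59.3 ± 0.936 TPM. Against siControl replicate 2 alone, 45 of the 70 were positive, the median was 0.08 and the list did not pass (adjusted p = 0.364). Of 79 cytosolic ribosomal protein genes, 67 were negative with a median of -0.09, 0 of them adjusted over the list alone (camera, adjusted p = 0.000438; adjusted p = 0.684 with an estimated correlation). Only 1 of the 79 was positive without siControl replicate 2 (median -0.28, adjusted p = 3.53e-17), 77 were positive against it alone (median 0.26, adjusted p = 2.37e-14), and the median was 0.01 after quantile normalization. The list did not pass without siControl replicate 1 (median -0.01, adjusted p = 0.0898) or 3 (median 0.00, adjusted p = 0.269). RPL22 was at 938 ± 181 and 736 ± 39.8 TPM and RPL38 at 1442 ± 199 and 1213 ± 133 TPM. The 13 mitochondrially encoded genes were all positive with a median of 0.75, 0 of them adjusted over the list alone (camera, adjusted p = 0.0131; adjusted p = 0.662 with an estimated correlation). Against siControl replicate 2 alone 2 of the 13 were positive, the median was -0.23 and the list passed as lower (adjusted p = 0.0172). Without that replicate the median was 1.18 (adjusted p = 3.12e-07), and without siControl replicate 1 or 3 it was 0.45 and 0.48 and the list did not pass (adjusted p = 0.0898 and 0.0826). MT-CO1, a subunit of cytochrome oxidase, was at 10181, 19184 and 9593 TPM in siControl and 19384, 23891 and 24058 in siNPM1, and MT-ND6 at 1038, 3553 and 920 against 3367, 3564 and 3756.

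Immediate early genes passed as a lower list (13 of 18 negative, median log2 fold change -0.60, 0 adjusted over the list alone; camera, adjusted p = 0.0255; adjusted p = 0.662 with an estimated correlation). Against siControl replicate 2 alone their median was 0.33 (adjusted p = 0.00189), and without that replicate -1.14 (adjusted p = 7.29e-06). Without siControl replicate 1 or 3 it was -0.31 and -0.25, and the list did not pass (adjusted p = 0.105 and 0.267). The median stayed about as large after centring (-0.73, adjusted p = 0.0986), quantile normalization (-0.57, adjusted p = 0.0683) and removal of GC and length trends (-0.74, adjusted p = 0.0594), where it did not pass. The member with the smallest p, FOSL1, went against the list and was higher in siNPM1 (log2 fold change 1.01, adjusted p = 0.216 in limma). IER3, the next by p, was at 155, 86.2 and 151 TPM in siControl and 24.1, 75.8 and 75.2 in siNPM1. Of the other stress lists, 0 passed in camera at the settings of the report. Among 35 p53 targets, 22 were positive and 0 passed adjusted over the list alone (camera, adjusted p = 0.576), with DRAM1 at 1.01 ± 0.431 and 3.79 ± 1.12 TPM and FBXO22 at 44.5 ± 2.77 and 60.8 ± 3.11 TPM. Among 21 interferon response genes, which can be induced by duplex RNA, 14 were positive and 2 passed adjusted over the list alone (camera, adjusted p = 0.0828). They were IFI6 and BST2, which encodes tetherin, at 33.7 ± 16.7 and 124 ± 22.6 TPM. The interferon list passed in camera without siControl replicate 1 (adjusted p = 0.0453) or 3 (adjusted p = 0.0297). It also passed without siNPM1 replicate 3 (adjusted p = 0.0309) and without a filter on low values (adjusted p = 0.0494). It did not pass without siControl replicate 2 (adjusted p = 0.579) or with an estimated correlation (adjusted p = 0.662). Against siControl replicate 2 alone 19 of its 21 genes were positive, with a median of 0.29. Of 20 unfolded protein response genes 12 were negative, with 0 adjusted over the list alone (camera, adjusted p = 0.07), with CANX at 202 ± 6.06 and 251 ± 17.4 TPM and DNAJC3 at 13.5 ± 2.19 and 9.22 ± 0.667 TPM. It passed as lower without siControl replicate 2 (adjusted p = 0.024), siNPM1 replicate 2 (adjusted p = 0.0123) or siNPM1 replicate 3 (adjusted p = 0.00986), and without a filter on low values (adjusted p = 0.0468). Of 28 hypoxia and glycolysis genes 18 were negative, with 0 adjusted over the list alone (camera, adjusted p = 0.194), and EGLN3 and MXI1 had log2 fold changes of 1.38 and -0.93. That list passed as lower without siControl replicate 2 (camera, adjusted p = 0.0082), while its median against that replicate alone was 0.20. With all 6 libraries and an estimated correlation it did not pass (camera, adjusted p = 0.662).

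Among lineage markers, neuroectoderm genes lay higher in siNPM1 as a list: 13 of 16 were positive with a median log2 fold change of 0.77. Over all genes 0 passed, and 3 passed adjusted over the list alone (camera, adjusted p = 0.0255; adjusted p = 0.662 with an estimated correlation; adjusted p = 0.115 without siControl replicate 2). The neuroectoderm median was about as large without siControl replicate 2 (0.77), with a mean of at least 5 TPM (0.76, adjusted p = 0.0577) and with array weights (0.65, adjusted p = 0.0802), where the list did not pass. Against siControl replicate 2 alone it was 0.39 (adjusted p = 0.422). NES, which encodes nestin and was chosen after its values were seen, was at 74.2 ± 8.76 and 131 ± 24.8 TPM (log2 fold change 0.80, adjusted p = 0.184 in limma). LHX5, a forebrain homeobox gene, was at 0.120, 0.430 and 0.0900 TPM in siControl and 9.04, 3.12 and 2.81 in siNPM1, and MAP2, a neuronal microtubule protein, at 0.180, 0.790 and 0.370 against 9.34, 3.46 and 3.41. Of 9 neural crest genes 6 were positive, with 1 adjusted over the list alone (camera, adjusted p = 0.389), and NGFR and ZIC1 had log2 fold changes of 0.97 and 0.69. The 14 trophoblast and amnion genes split 7 to 7, with 0 adjusted over the list alone (camera, adjusted p = 0.662), with GABRP at 108 ± 13.7 and 76.0 ± 5.73 TPM and KRT7 at 3.52 ± 0.106 and 6.86 ± 2.44 TPM. Of 9 mesoderm and primitive streak genes 5 were positive, with 1 adjusted over the list alone, TBX3 (camera, adjusted p = 0.631), and ACTC1 was at 17.8, 5.01 and 17.6 TPM against 3.01, 3.81 and 3.68. Of 13 fibroblast and mesenchymal genes 9 were negative, with 2 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.134; adjusted p = 0.0302 without siNPM1 replicate 2). COL1A1 and FN1 had its smallest p. Definitive endoderm, with 4 tested members, all positive, and the HOX A and B clusters, with 1, were too small to test. Of these, HHEX and FZD8 had log2 fold changes of 1.18 and 1.49, and HOXB2 of -0.10.

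In all, camera passed 10 of the 27 lists, 4 higher and 6 lower. With an estimated correlation 0 lists passed, with adjusted p from 0.662 to 0.723. Fry passed 3 lists, all higher, p53 targets (adjusted p = 0.00682), WNT targets (adjusted p = 0.0484) and neural crest (adjusted p = 0.0484), none of them among the 10. Unlike camera, fry tests the members against no change and not against the other genes. The median log2 fold change over all tested genes was 0.10, so a positive shift shared by many genes counts toward higher in fry. For pluripotency, trophoblast and amnion, BMP ligands, receptors and antagonists, and mesoderm and primitive streak, camera's direction was lower while the median was positive. ATF4 targets, cholesterol synthesis, and G2 and mitosis passed as lower without siControl replicate 2. Against it alone their medians were also negative, at -0.15, -0.10 and -0.15. These fits share the siNPM1 libraries. With all 6 libraries and an estimated correlation none of the 3 lists passed (camera, adjusted p = 0.662 for each).

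**Figure D3:**
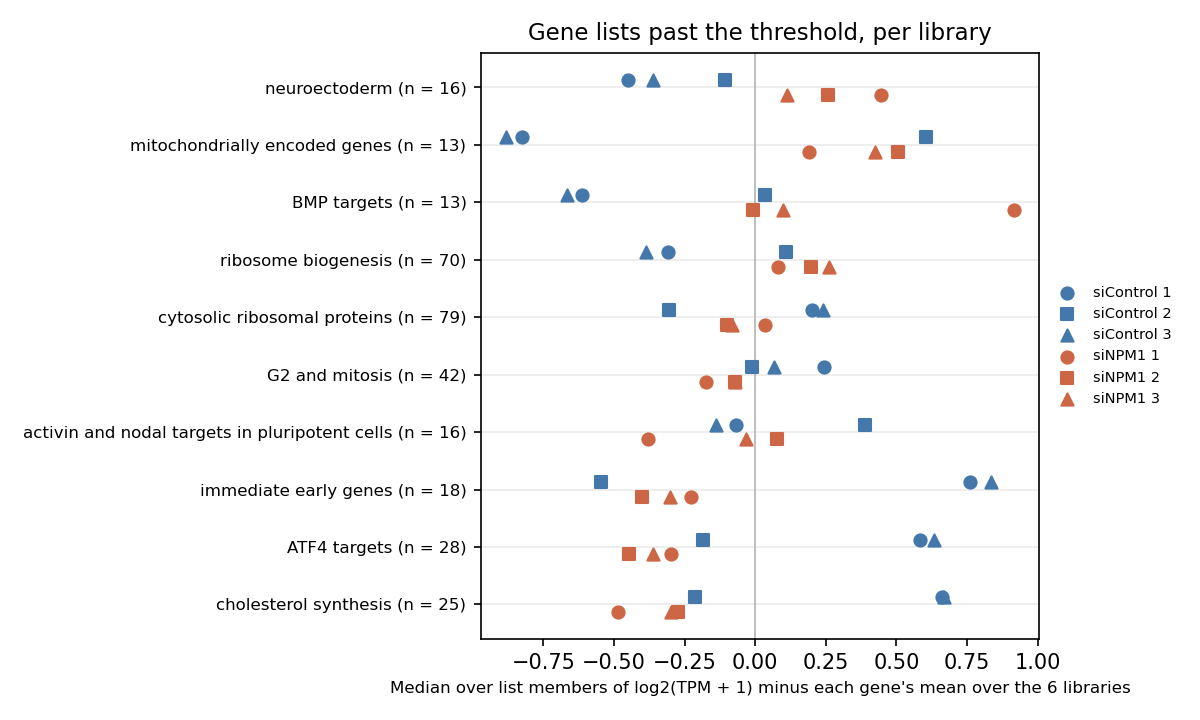
Median over the tested members of each of the 10 lists past the threshold, on the log2(TPM + 1) scale relative to each gene's mean over the 6 libraries, 1 point per library, coloured by group and shaped by replicate. For ATF4 targets siControl replicates 1 and 3 lie at 0.584 and 0.634, siControl replicate 2 at -0.186 and the siNPM1 libraries between -0.447 and -0.300.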

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

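The fit with siControl replicate 2 as the only control and the fit with GC and length trends removed were chosen after the data were seen; the other alternatives were set before. The log2 fold change of NPM1 lay between -3.91 and -4.18 over all alternatives and passed in all but 1, siControl replicate 2 as the only control (-3.96, adjusted p = 0.0651 in limma, where the range over the others was 9.94e-05 to 0.0244). The count of 4 genes past the threshold, all lower, was 3 or 4 under pseudocounts of 0.1 and 0.5, centring, quantile normalization, rescaling without mitochondrial and ribosomal protein genes, a robust prior, GC and length trends removed and a minimum log2 fold change of 1. It was 2 under a pseudocount of 5 and under a mean of at least 5 TPM, and 1 without a filter on low values, where 33001 genes were tested; all of these were lower. Without a trend in the prior variance 7 passed, 3 of them higher. With array weights, which gave siControl replicate 2 a weight of 0.0977 against 4.45 and 1.20 for the other siControl libraries, 9486 passed, 5771 higher and 3715 lower. With siControl replicate 2 as the only control 27 passed, all lower. Leaving out each library in turn gave 1 to 5833 genes, 0 to 3805 higher and 1 to 2028 lower. The highest values came without siControl replicate 2; the others were 1 to 11.

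The replicate number as a block left 1 gene past the threshold, lower in siNPM1, and 11 lists, with S phase among them (adjusted p = 0.0378). The labels give no pairing, and the deviations of same-numbered libraries from their group means correlated at 0.0652, 0.0814 and -0.0383 over genes. Over all pairs of a siControl and a siNPM1 library these correlations ran from -0.0851 to 0.0814. The largest, 0.0814 and 0.0652, were of same-numbered libraries, while siControl replicate 3 correlated best with siNPM1 replicate 1 (0.0641). Values this small, from deviations that sum to 0 within each group, can neither show nor exclude a pairing. The numbers were not taken to pair the samples because the labels give no pairing.

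The 10 lists past the threshold in camera became 8 to 13 under the other fits, 3 with fry and 0 with an estimated correlation. These were not always the same lists: 11 passed without siControl replicate 2, and only 7 of the 10 were among them in the same direction. With siControl replicate 2 as the only control, the direction turned for ribosomal proteins (median log2 fold change 0.26), mitochondrially encoded genes (-0.23), immediate early genes (0.33), S phase (-0.27), YAP targets (0.39) and hypoxia and glycolysis (0.20). Ribosomal proteins also turned under quantile normalization (0.0121). For these turns the cause was not tested. Of the 71 named genes other than NPM1, 0 passed with all 6 libraries at the settings of the report, 62 passed without siControl replicate 2 and 68 with array weights. Results not past the threshold in either fit were not given a direction: their sign differed in 37 cases over 10 lists and in 11 cases over 4 genes. Depth is unknown, so what it limits cannot be stated.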

Other observations

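The counts over splits, the count of separated genes, the fit against siControl replicate 2 alone and the tests of explanations were chosen after the results were seen, while limma and camera on all 6 libraries, with either correlation, were set before. With genes of the report among them, 50 genes lay over 2-fold apart in TPM + 1 in every pair of siControl and siNPM1 libraries, 30 higher and 20 lower. The higher ones include ENSG00000286054, ENSG00000286057 and ENSG00000286091, whose values are identical in every library, so these entries are not separate observations. NPM1 and its pseudogenes NPM1P46 and NPM1P51 are among the lower ones. None of those below, which are not in the report, passed the threshold in limma, and they were chosen after their values were seen. COL2A1, a cartilage collagen, was at 7.43, 6.49 and 8.29 TPM in siControl and 1.34, 1.96 and 2.25 in siNPM1 (adjusted p = 0.105). TMEM106C was at 119, 47.1 and 99.2 against 21.0, 17.8 and 19.8 TPM (adjusted p = 0.149), and ACTA1, the skeletal muscle actin, at 69.4, 12.5 and 70.5 against 0.370, 3.51 and 4.20 (adjusted p = 0.179). On the higher side, NTN1, which encodes netrin, was at 1.15, 0.900 and 1.14 against 6.88, 4.13 and 3.68 TPM (adjusted p = 0.164), and FLRT3 at 0.0200, 0.360 and 0.0200 against 4.00, 1.79 and 2.07 (adjusted p = 0.173). Another split, siControl replicates 1 and 3 with siNPM1 replicate 1 against the rest, also gave 50 such genes, and the remaining splits gave 5 to 15.

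Single members of the fixed lists stood apart in siNPM1 replicate 1; they were chosen after their values were seen and not tested. ID1, a BMP target, was at 282 TPM in it and 52.0 and 47.8 in siNPM1 replicates 2 and 3, and ID4 at 19.7 against 3.16 and 3.27. LEFTY1, a nodal target, was at 0.470 against 12.5 and 8.52 TPM, and NODAL at 1.38 against 9.52 and 7.56. EGR1, an immediate early gene, was at 48.2 against 1.41 and 1.49 TPM. Other members did not stand apart: ID3 was at 158 against 141 and 133 TPM, and the immediate early gene IER2 at 54.1 against 55.5 and 56.1. In siControl, LEFTY1 was at 1.35, 59.5 and 1.27 TPM and NODAL at 9.59, 30.6 and 6.95, with siControl replicate 2 the highest.

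The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4 genes past the threshold, with 2 of the 10 splits as high and 9 the highest of the others. For higher genes it gave 0 (10 of 10 as high, highest other 6), for lower genes 4 (2 of 10, highest other 6), and for lists 10 (5 of 10, highest other 14).

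siControl replicate 2 lay nearer to the siNPM1 libraries than to siControl replicates 1 and 3. A library of knocked-down cells under a control label is argued against, because NPM1 stood at 95.1% of the level in replicates 1 and 3. GC and length trends accounted for 2.36% of the variance of its log2 difference from those replicates, over the 96.5% of tested genes with both values. For a different part taken by mitochondrial and ribosomal protein transcripts, rescaling without them left 123.6% as many other genes over 2-fold apart in TPM + 1. That value cannot decide the question. Rescaling moves all other genes of a library by the same factor, and it raises low values against the unchanged pseudocount. A preparation, culture state or batch shared with the siNPM1 libraries stays open, because the labels give no batch and the correlation of siControl 2 minus siControl 1 with siNPM1 minus siControl 3 (0.666 over genes) only restates the pattern; no biological explanation was tested.

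Most detected pseudogenes of NPM1 were low in siNPM1. Of 49 in the table, 9 had a mean of at least 0.5 TPM in either group, all 9 had a lower mean in siNPM1, 2 of them passed, and the median level left was 11.49% beside 6.26% for NPM1, while NPM1P26, NPM1P7 and NPM1P9 kept 55.5%, 61.8% and 62.0% with overlapping groups. Reads of NPM1 assigned to its pseudogenes may account for the low ones. The small interfering RNA may also act on pseudogene transcripts: its sequence is not given in the sources used here, so this cannot be told apart. NPM1P51, at 6.45% of its siControl level, shared 0% of its 50-base stretches exactly with NPM1, so exact multiple matches of that length do not account for it.

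ATF4 targets, cholesterol synthesis and G2 and mitosis were the lists that passed as lower against either set of controls, in fits that share the siNPM1 libraries. The distance of siControl replicates 1 and 3 from the other libraries may carry most of the first 2, whose medians shrank to -0.15 and -0.10 against siControl replicate 2. All 3 lists still passed there with the preset correlation (adjusted p = 0.0293, 0.0293 and 3.69e-05), but none with an estimated one (adjusted p = 0.708, 0.708 and 0.638). Members that vary together across libraries may therefore account for these calls: with 6 libraries the smallest adjusted p of the 3 with an estimated correlation was 0.662. An effect of lowering NPM1, the biological explanation the design gives, cannot be told apart from these.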
